A study of Komagataella phaffii GS115 with 2 samples.

How the data were processed

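Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of H3K36me3, a trimethylated lysine of histone H3, was performed in wild-type cells of Komagataella phaffii GS115. This strain belongs to a methylotrophic yeast species long known as Pichia pastoris. Per the labels' protocols, shaken cultures were fixed with formaldehyde, ground in liquid nitrogen and sonicated, and the chromatin was incubated with an H3K36me3 or an H3 antibody. Input chromatin was also kept, per the labels' protocols. The labels list 2 H3K36me3 libraries of 1 group and give no carbon source. The input and H3 libraries were not analysed here.

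The data used here were 1 table with 1 column of FPKM values (fragments normalised to gene length and to a total of fragments). They were calculated by the authors for 5040 genes and deposited with the H3K36me3 library of replicate 1. The column name, per the file headers, carries no replicate number, and whether the second library was pooled or averaged into it is not given in the sources used here. No separate values of the second library were used, so no replicate error could be calculated, and every interval below describes the spread over genes and not over cultures. FastQC 0.12.1, Trimmomatic 0.39, Bowtie2, SAMtools, deepTools and MACS2 are named, with no roles, per the submitters' processing notes. The counting tool, the genome build and the annotation are not given in the sources used here. The values are not relative to input or H3, so a gene's FPKM also carries unenriched background fragments, its nucleosome density, its copy number and how well fragments map to it.

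All 5040 identifiers matched a locus tag in the RefSeq gene table of assembly ASM2700v1, in the same order as in the deposited file. Because the authors' build is not named, that table was used for gene order, overlap of adjacent genes, chromosome and gene length, and no coordinate is given. Of the gene lengths, 92.2% were multiples of 3, as coding lengths without untranslated regions are, and 393 genes had other lengths. The table has no exons, so whether a length includes introns is not known. Multiplied by these lengths and added up, the deposited FPKM values came to 100.1% of the sum that arises when the scaling total is the number of fragments counted in these genes. Such scaling fixes the length-weighted mean, so the values rank genes against one another and give no absolute level of the mark. A search for the value of 1 read over totals from 100000 to 300000000, in the 300 genes with the fewest implied fragments and a length that is a multiple of 3, found no common step. At the best total 10.7% of all 5040 genes came within 0.05 of a whole read, where chance gives 10%. The sequencing depth is therefore unknown, and no counting interval is given.

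Values were analysed as log2(FPKM + 1) where a difference is given on the log2 scale. The relation with gene length was measured with Spearman's rho across genes and with medians over 10 classes of equal size by length, with 95% intervals from 1000 bootstrap samples of genes. For position, each group's median was compared with the median of all genes, and its percentile was taken among 10000 random lists of the same size matched on length in 10 bins. A group was taken to stand apart outside percentiles 2.5 to 97.5. Adjacent genes were compared by Spearman's rho, with an interval from 500 bootstrap samples of pairs, against 1000 shuffled orders within chromosomes. Genes are not independent replicates, so no p-value is given. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

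The comparison of group medians, the neighbour correlation, the correlation with length and the slope of spread on length were tested on simulated data over the 5040 genes. Lists of 80 genes lowered by 0.05 on the log2 scale stood apart in 45% of 40 simulations, and lists lowered by 0.1 in 100% of them. Unchanged lists of 80 stood apart in 7.5%. These lists held scattered genes, in values shuffled so that adjacent genes were not alike. The rates may therefore not hold for groups of adjacent genes. A simulated neighbour correlation of 0.3 was estimated at 0.29.

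Some analyses fixed before the data were examined could not be run. The gene table pairs locus tags with no product, gene name, strand, exon or sequence, so the 25 gene lists planned on product names, the comparison of genes with and without introns, the orientation of neighbours and matching on GC content were left out. The planned distance to a chromosome end was replaced by the number of genes from the end. The planned rule named the 10 highest and the 10 lowest genes of at least 500 nt. Because no gene has a name beyond its locus tag, the 2 highest and the 2 lowest are given by locus tag and the others are summarised. The alternatives tried were other pseudocounts, unmatched lists, a filter on FPKM, a minimum length and leaving out the outermost genes.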

Results

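The series asked where H3K36me3 lies on the genome of Komagataella phaffii GS115, a yeast that grows on methanol and is widely used to produce recombinant proteins. H3K36me3 is a modification of histone H3 that, in budding yeast, is laid down over transcribed gene bodies by the methyltransferase Set2 as it travels with RNA polymerase II. The labels describe 2 ChIP libraries of wild-type cells in 1 group, with no other condition. The values analysed are 1 set of FPKM values over 5040 genes on 4 chromosomes, deposited with replicate 1. The sequencing depth is unknown and there is no replicate error. The comparisons below are therefore between genes within this set of values.

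Fragments of the H3K36me3 ChIP were counted over every listed gene, and FPKM was nearly even across the gene set. The median was 138 FPKM, with quartiles at 126 and 148 FPKM, and no gene was listed at 0 or under 1 FPKM. The coefficient of variation over genes was 14.5% (mean 136 ± 19.7 FPKM, SD over 5040 genes), and 91.7% of genes lay within 25% of the median. The 95th percentile, 164 FPKM, was 1.62 times the 5th percentile, 101 FPKM (bootstrap 95% interval of the ratio over genes, 1.59 to 1.65). Only 2 genes exceeded 2 times the median, and 12 genes lay below 0.5 of it. The distribution had a longer lower side, with 305 genes more than 25% below the median and 112 genes more than 25% above it. This asymmetry lay in the genes of at least 500 nt. Among these 4513 genes, 242 were more than 25% below their median of 139 FPKM and 41 were more than 25% above it. Among the 527 shorter genes the corresponding numbers were 58 below and 79 above their median of 137 FPKM. The values are not corrected for input or for H3, so these levels combine the mark with unenriched background fragments, nucleosome density and copy number, and do not show whether a given gene carries the mark.

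**Figure D1:**
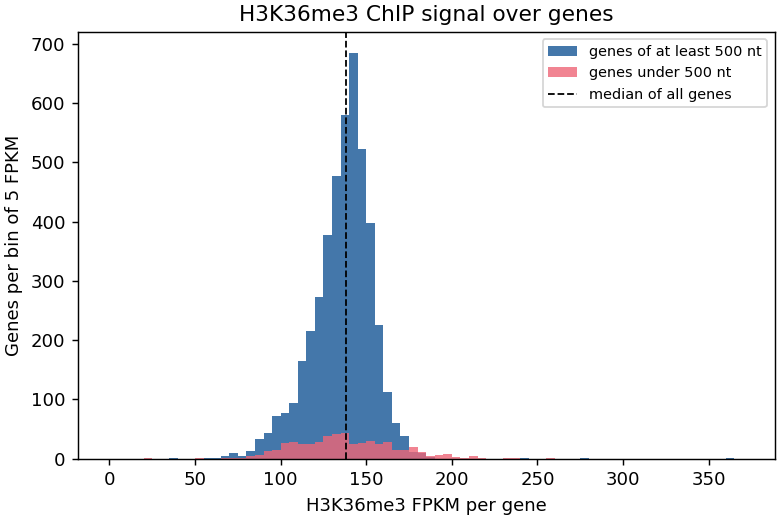
Histogram of H3K36me3 FPKM per gene (x axis) against the number of genes per bin of 5 FPKM (y axis), for 4513 genes of at least 500 nt and 527 shorter genes, with the median of all genes as a dashed line at 138 FPKM. The genes form a single peak, with 91.7% of them within 25% of the median, and the genes of at least 500 nt tail further to low than to high values.

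The 2 highest and the 2 lowest genes of at least 500 nt lay beside genes with values near the median. The highest value belonged to PAS_chr2-2_0376, a gene of 714 nt on chromosome 2, at 363 FPKM or 2.62 times the median of all genes. The genes on either side of it had 132 and 135 FPKM. The second highest, PAS_chr1-1_0219 on chromosome 1 (825 nt), had 279 FPKM, 2.02 times the median, between neighbours at 138 and 148 FPKM. It was not alone in its stretch: the genes 3 and 2 places before it had 240 and 182 FPKM. The 10 highest genes of at least 500 nt ranged from 183 to 363 FPKM and had a median length of 699 nt. The lowest gene of at least 500 nt was PAS_c131_0020 (1704 nt), the last annotated gene of chromosome 3, at 37.1 FPKM or 0.27 times the median, beside a neighbour at 153 FPKM. The next lowest, PAS_chr2-2_0003 (1524 nt), was the last annotated gene of chromosome 2, at 55.7 FPKM or 0.40 times the median, beside a neighbour at 126 FPKM. The 10 lowest genes of at least 500 nt ranged from 37.1 to 70.2 FPKM, had a median length of 867 nt, and 5 of them were among the outermost 10 genes of a chromosome end. The lowest value over all lengths, 20.3 FPKM, was that of a gene of 195 nt in the interior of chromosome 1. Without a second set of values these single-gene levels have no replicate check.

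Longer genes had slightly higher FPKM in the H3K36me3 ChIP and varied far less. Genes were divided by length into 10 classes of 504 genes. The longest class, 2625 nt and above, had a median of 143 FPKM (bootstrap 95% interval 142 to 143). The second shortest class, from 488 to 677 nt, had a median of 134 FPKM (132 to 137), the lowest of the 10 classes. The difference between these medians was 6.58% (interval 4.02% to 8.48%). That interval does not allow for having the lowest class as the baseline. The shortest class, from 138 to 486 nt, did not continue this order, with a median of 136 FPKM (134 to 138). Across all genes Spearman's rho between FPKM and gene length was 0.12 (interval 0.09 to 0.15). The SD over genes was 31.1 FPKM in the shortest class and 9.70 FPKM in the longest class. The number of genes more than 25% below the median of all genes was 60 in the shortest class and 3 in the longest. The number more than 25% above it was 69 in the shortest class and 1 in the longest. FPKM divides by length, so part of any trend with length can come from the length used, and the authors' own gene lengths are not given in the sources used here.

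**Figure D2:**
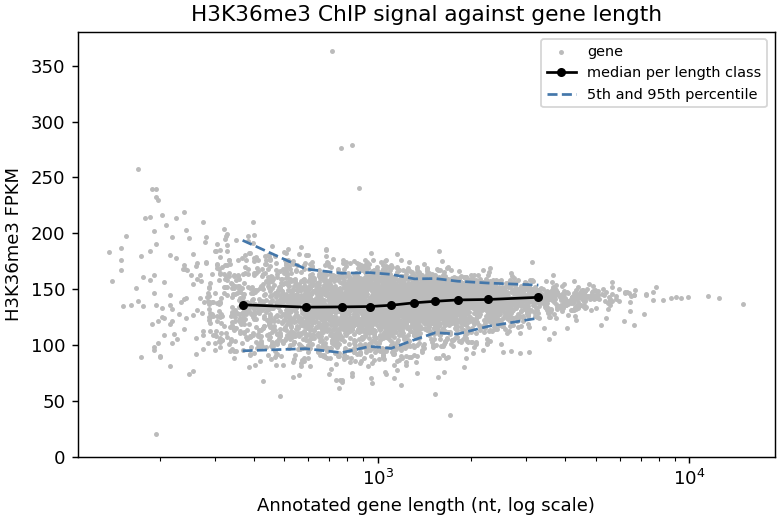
H3K36me3 FPKM (y axis) of each of 5040 genes against annotated gene length in nt (x axis, log scale), with the median and the 5th and 95th percentiles of each of 10 length classes drawn at its median length. The median rises from 134 FPKM in the second shortest class to 143 FPKM in the longest, and the band between the percentiles narrows.

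The 4 chromosomes had almost the same median signal. Chromosome 3 had the highest median, 139 FPKM over 1198 genes, at percentile 88.2 of random lists matched on length. Chromosome 2 had the lowest, 137 FPKM over 1333 genes. It was the one chromosome to stand apart from random lists matched on length, at percentile 0.365, although its difference from all genes was only -0.011 on the log2 scale. Chromosomes 1 and 4, with 1538 and 971 genes, had medians of 138.5 and 138.7 FPKM, at percentiles 60.5 and 81.5.

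Genes near chromosome ends had a median close to that of the interior. The outermost 10 genes of each of the 8 ends, 80 genes in all, had a median of 135 FPKM, a difference of -0.03 on the log2 scale at percentile 10.7 of random lists. The 120 genes from the 11 to the 25 place had a median of 136 FPKM at percentile 5.44. The 200 genes from the 26 to the 50 place had a median of 138 FPKM at percentile 32.1. None of these groups stood apart by its median. In the outermost 10 genes, 14 of 80 (17.5%) lay more than 25% below the median of all genes, against 6.05% of all genes. That count was looked at after low genes had been found there, and chance was not settled, as given below. Lists of the outermost 5 and 20 genes, chosen after the data were examined, fell just past the limit, at percentiles 2.32 and 2.28. The random lists here, and those for the chromosomes, drew scattered genes, whereas these groups are runs of adjacent genes. Adjacent genes were weakly alike, as given below, so the limits may be too narrow. The outermost annotated genes at the starts of chromosomes 1 to 4 had 130, 129, 145 and 184 FPKM, and those at their ends had 96.1, 55.7, 37.1 and 143 FPKM.

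Adjacent genes had weakly similar FPKM in the H3K36me3 ChIP. No similarity past that of shuffled orders was detected at 2, 3, 5 or 10 places apart. Spearman's rho over 5036 adjacent pairs was 0.14 (bootstrap 95% interval 0.12 to 0.17), above the highest of 1000 shuffled orders, 0.049. For genes 2 places apart rho was 0.025, inside the middle 95% of shuffled orders, which ran from -0.027 to 0.026. At 3, 5 and 10 places apart rho was 0.012, 0.021 and 0.00998, each also inside that range for its distance. Pairs of genes under the median length of 1197.5 nt had a rho of 0.22 (0.17 to 0.27, 1306 pairs). Pairs of genes at or above it had a rho of 0.039 (-0.018 to 0.096, 1305 pairs), inside the range of shuffled orders. Pairs with 1 gene on each side of the median length had a rho of 0.12 (0.079 to 0.16, 2425 pairs). That value was above the highest of shuffled orders, 0.079. The lowest running median of 11 genes, on chromosome 3, was 101 FPKM, at percentile 0.9 of the lowest running median in shuffled orders. That stretch was mixed, with 7 genes below the median of all genes and 4 above it, from 68.7 to 158 FPKM. Shuffled orders also lack the resemblance of adjacent genes, so the percentile does not test for a low stretch beyond it.

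**Figure D3:**
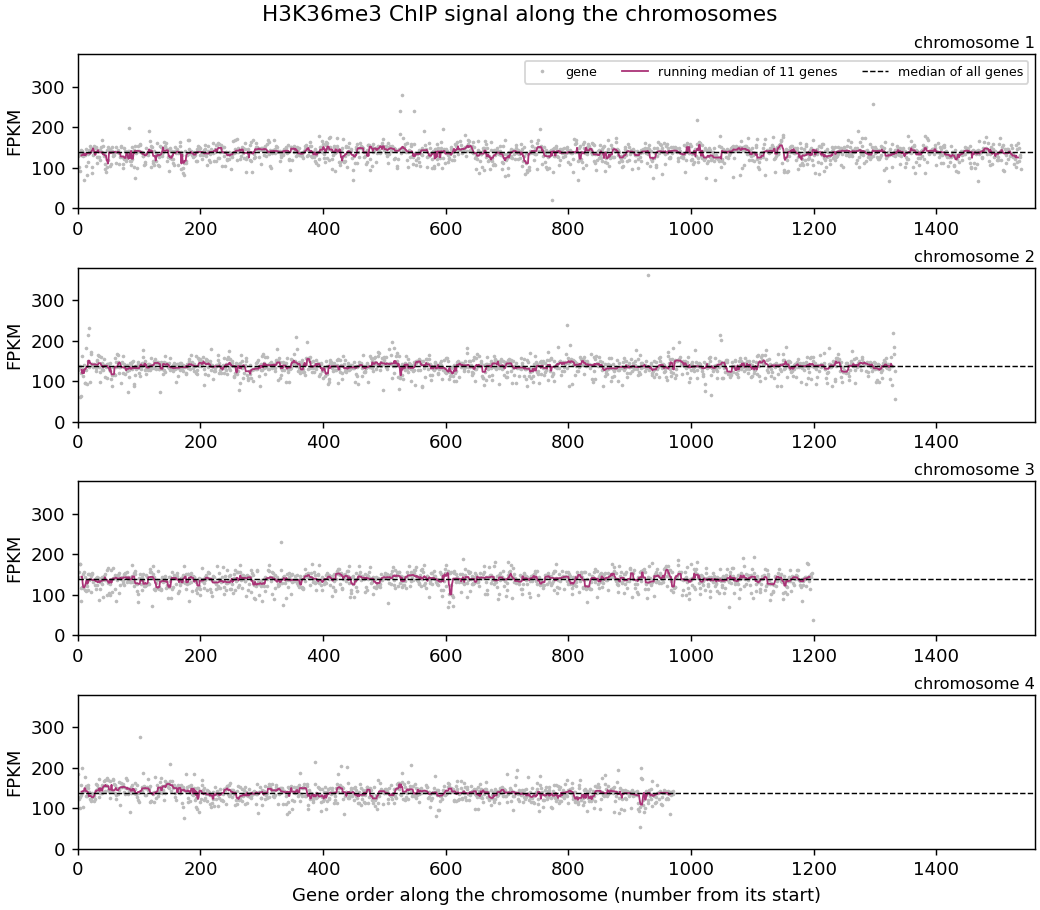
H3K36me3 FPKM (y axis) of each gene against its order along chromosomes 1 to 4 (x axis, gene number from the start), with a running median of 11 genes and the median of all genes, 138 FPKM, as a dashed line. The running median ranges from 101 to 162 FPKM, and both extremes lie on chromosome 3.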

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

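No paired analysis was possible because the values form 1 column of 1 group. Leaving out each replicate, the agreement of replicates, matching on GC content, and all alternatives for the gene lists, introns and orientation of neighbours were not run. The filter at 1 FPKM removed no gene and so tests nothing for the 10 results it was applied to. Restricting to genes of at least 500 nt moved the ratio of the 95th to the 5th percentile from 1.62 to 1.56 and rho with gene length from 0.12 to 0.16, each outside its bootstrap interval over genes, and the cause was not tested. The same restriction took chromosome 3 past the upper limit, with a difference from all genes of 0.0095 on the log2 scale at percentile 97.7. Taking the outermost 5 or 20 genes in place of 10, settings added after the data were examined, gave differences of -0.067 and -0.030 on the log2 scale and crossed the lower limit; the cause was not tested. The other 43 values under alternatives, those of the 1 FPKM filter included, kept their side of the limits or stayed inside the interval, among them the neighbour correlation without overlapping pairs (0.14) and after removing a trend with gene length (0.16), both added after the data were examined. The genes 26 to 50 places from an end, which did not stand apart, changed sign to 0.0035 when only genes of at least 500 nt were used. Depth is unknown, so what counting error adds to short genes could not be set apart.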

Other observations

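The test of long adjacent pairs was set before its comparison with shuffled orders was seen. Running medians were not among the planned analyses. The tests of lengths that are not multiples of 3, of low genes near chromosome ends, of a broad trend along the chromosomes and of the slope of spread on length were chosen after the data were examined. Genes whose length is not a multiple of 3 had a median of 138 FPKM over 393 genes, at percentile 31.3 of random lists matched on length, inside the limits. Among running medians of 11 genes, the lowest was 101 FPKM, on chromosome 3 over genes 602 to 612 of 1198. It was at percentile 0.9 of the lowest value in 1000 shuffled orders, which lack the resemblance of adjacent genes. Of these 11 genes, 7 lay below the median of all genes and 4 above it. The highest running median was 162 FPKM, on the same chromosome over genes 955 to 965, at percentile 96.5 of the highest value in shuffled orders.

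Of the outermost 10 genes of each chromosome end, 14 of 80 (17.5%) lay more than 25% below the median, against 6.05% of all genes. This number was at percentile 99.97 of random lists matched on length and 99.94 of random runs of 10 adjacent genes. Among random lists the percentile was at least 99.77 with any 1 end left out, 99.7 without the last gene of every end and 100 for the 67 of these genes of at least 500 nt, 13 of them low. The count was looked at after 5 of the 10 lowest genes of at least 500 nt had been found there. With those 10 lowest genes not counted, 9 remained, against a mean of 4.69 in random runs and 4.91 in random lists. This number was at percentile 95.7 of random runs and 96.1 of random lists, inside the limits. Leaving out genes that were low and lay at the ends had to lower the count. Chance was therefore not settled either way. Fragments that map to several near-identical end sequences, fewer nucleosomes, or less H3K36me3 at some genes may each give such a pattern and stay open too, since neither sequence, input nor H3 was used.

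The resemblance of adjacent genes may come from fragments near gene ends, or from signal shared over a short distance. The rank correlation was 0.039 for pairs of long genes, under the upper limit of the middle 95% of shuffled orders (0.057). Fragments counted for both neighbours would give such a low value in long pairs. Signal shared over a distance that is short beside long genes could give it too. The low value in long pairs therefore does not tell these 2 explanations apart. Pairs of 1 long and 1 short gene had 0.12, above the highest of shuffled orders (0.079). Overlapping annotations do not account for the resemblance, since rho without the 75 overlapping pairs was 0.14. A broad trend along the chromosomes, such as copy number or large domains, is argued against, as the source of the average resemblance, by the ratio of the correlation 2 places apart to that of adjacent genes, 0.16 (block bootstrap interval -0.076 to 0.36). Shared transcription, background, nucleosome density, mapping and GC content of neighbouring genes were not tested.

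The narrowing of values with gene length had a slope of -0.63 between the log2 relative spread and log2 length over the 10 length classes when spread was taken from the interquartile range (interval -0.70 to -0.57), and of -0.54 when it was the SD over the mean (-0.58 to -0.49). At an even FPKM, counting noise alone, or the averaging of independent local signal alone, would give -0.5. In simulated data with a slope of -0.5, the interquartile measure gave -0.52 on average. The first interval leaves out -0.5, which goes against either explanation alone by that measure, and the second interval holds it. The measures disagree, so neither explanation was settled. Both would give the same slope, so the slope cannot tell them apart. The size of the spread was not compared with that of counting noise, since the sequencing depth is unknown. The search for the value of 1 read found no common step, so counting noise was not tested from read counts. No biological explanation was tested.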
